A study of Sinorhizobium meliloti with 6 samples.

How the data were processed

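RNA sequencing covered 6 libraries of free-living Sinorhizobium meliloti, a soil bacterium that forms nitrogen-fixing nodules on legume roots. According to the labels, 3 libraries came from the wild-type strain 1021 (a, b and c) and 3 from its derivative RD64 (d, e and f), which overproduces indole-3-acetic acid (IAA), the main natural auxin. The cells were in exponential growth. Per the labels' protocols, the large ribosomal RNAs were depleted and the poly-A selection step of the library kit was skipped. The protocols name a rich and a minimal medium and mention a low-oxygen incubation and added glutamate in some experiments, without saying which of these applied to the sequenced cells. The labels also do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be partly technical. The labels of 5 libraries refer to a table of those 5, and wild type a carries no such reference. No other label of a batch or date was given.

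The authors deposited 1 table of normalized read counts, a signal with 1 column per library and 1 row per feature, and replicates were not pooled. The submitters' processing notes name Bowtie, Bowtie2, bedtools and DESeq, with no version, role or order. The genome build, the annotation, the treatment of reads that map to several places and the use of strand were not given in the sources used here, so overlapping genes and near-identical copies may share reads. The table held 6346 rows. All values (100%) lay within 0.0001 of a whole multiple of 1 step per column, so each deposited value is a whole read count divided by 1 factor per library. The deposited factors matched DESeq2 size factors recomputed from the recovered reads to within 3.0e-10 on the log2 scale, and values were not adjusted for gene length. The step of RD64 d was 0.999, close enough to 1 that a rule based on low values alone would not tell it from rounding, but its values carry 9 decimals. Column order and values played no part in assigning libraries: the column names are the sample titles.

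Of the rows, 54 carried protein accessions and each repeated the values of the row above it in all 6 libraries, so they were treated as second listings and left out, leaving 6292 rows with locus tags. Recovered reads per library ranged from 3544224 (wild type a) to 7234580 (RD64 e). The limit of precision this sets is that a gene with no reads in a library could still hold up to 3 reads' worth of expression. Confidence intervals below are exact binomial intervals for the share of genes called. They treat genes as independent and do not cover variation between libraries.

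Strain difference was tested with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided) on log2(normalized read count + 1), over genes with a mean of at least 10 normalized reads across the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes, and are given as RD64 minus wild type. Genes were assigned to replicons by locus tag prefix: SMc for the chromosome, SMa for the megaplasmid pSymA and SMb for the megaplasmid pSymB. The 3 replicons were compared with limma's camera test at a preset inter-gene correlation of 0.01, adjusted over the 3 sets, and again with an estimated correlation. Neighbouring genes were taken in the order of the deposited table, in which protein accession numbers rise within each replicon. Runs of at least 3 neighbouring tested genes called in one direction were counted and compared with 10000 permutations of the calls within each replicon. Single values of the 2 strains were compared with exact two-sided permutation tests, which cannot fall below 0.10 for 3 against 3 libraries.

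Before the data were examined, 23 lists of genes by symbol (nitrogen fixation, oxygen response, central metabolism, stress and others) had been fixed. None of the deposited IDs (0 of 6346) matched the gene table at hand, which describes another strain, CCBAU 71714, on assembly ASM3006458v1. The files do not pair locus tags with gene names, so these lists have 0 matched members and were not tested, and no gene is named by symbol. Likewise no row was known to be ribosomal or transfer RNA, and the transferred IAA pathway genes are not analysed here. For the same reason the fixed rule for named genes was applied without its requirement of a gene name: among genes past the threshold with a mean of at least 50 normalized reads and no overlap between strains, the 2 with the highest and the 2 with the lowest fold change are given by locus tag.

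Alternatives were other pseudocounts, filters, scalings (equal totals, quantile normalization), library quality weights, each library left out in turn, a stricter threshold, and count models on the recovered reads (edgeR 4.0.16 quasi-likelihood with TMM, and DESeq2 1.42.0). Keeping the repeated rows, thinning libraries to equal depth and leaving out wild type a and RD64 d together were added after the data were seen, as were the bins along the replicons, the runs, the segment of pSymA, the correlations of differences between libraries, the counts for the chromosome and pSymB without single libraries, and the fold changes of called pSymA genes without single libraries. The procedure was tested on simulated counts drawn from the means and dispersions of the 6012 tested genes with 200 genes changed. For this comparison limma recovered 74% of simulated 1.5-fold changes, 94% of 2-fold changes and 100% of 4-fold changes, and 5.18% of its calls were unchanged genes. With no simulated change it made 0 calls. Each gene was simulated independently, without variation shared between the genes of a library, so these shares may not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.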

Results

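The transcriptomes of free-living Sinorhizobium meliloti 1021 (n = 3 libraries) and of its IAA-overproducing derivative RD64 (n = 3) were compared by RNA sequencing. The question posed by the study is how overproduction of IAA in free-living rhizobia relates to the physiological state needed for nitrogen fixation in root nodules. The recovered reads assigned to genes came to 3544224, 6686754 and 5557107 in wild type a, b and c, and to 5997242, 7234580 and 6949485 in RD64 d, e and f. Between 6171 and 6185 of the 6292 genes had at least 1 read in each library. The single most abundant gene took 4.64% to 5.63% of normalized reads, and the 10 most abundant took 12.4% to 13.9%. The genome of this species consists of a chromosome and the megaplasmids pSymA and pSymB, and pSymA carries most of its known nodulation and nitrogen fixation genes.

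Libraries of one strain resembled each other slightly more than libraries of different strains, with some overlap. Over the 6012 genes tested, the correlation of log2 values across genes ranged from 0.987 to 0.995 within strains and from 0.980 to 0.988 between strains. The first principal component held 47.1% of the variance and separated the strains, with wild type at -9.70, -16.0 and -9.41 and RD64 at 15.7, 10.8 and 8.63. The second held 21.0% and mainly set wild type a (11.5) apart from wild type c (-15.6). Replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 5.10 to 16.8.

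RD64 differed from the wild type in 545 of 6012 genes (9.07%), and genes higher in RD64 outnumbered those lower. In RD64, 393 genes were higher and 152 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were modest: the median was 1.56-fold among the higher genes and 1.36-fold among the lower ones. Changes of at least 1 on the log2 scale were called for 64 higher genes and 10 lower genes. The normalized counts of the strains did not overlap in 544 of the 545 called genes, and in 31.6% of all tested genes, where chance gives 10%. Calls became more frequent with expression level, from 2.33% of the 1503 genes with the lowest means to 16.1% of the 1503 with the highest, as the median standard error fell from 0.203 to 0.0895. When libraries were rescaled to equal totals, 347 genes were higher and 230 lower, and with quantile normalization 343 and 233, so the share of higher genes among the calls fell from 72.1% to 60.1% and 59.5%. The number of calls was 222 without wild type b, 331 without RD64 d, 150 without RD64 e and 341 without RD64 f, and it stayed within 1.5 times the full count without wild type a (450) or wild type c (687). Lower genes numbered 45, 50, 19 and 48 in the first 4 of these fits and 279 without wild type c.

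**Figure D1:**
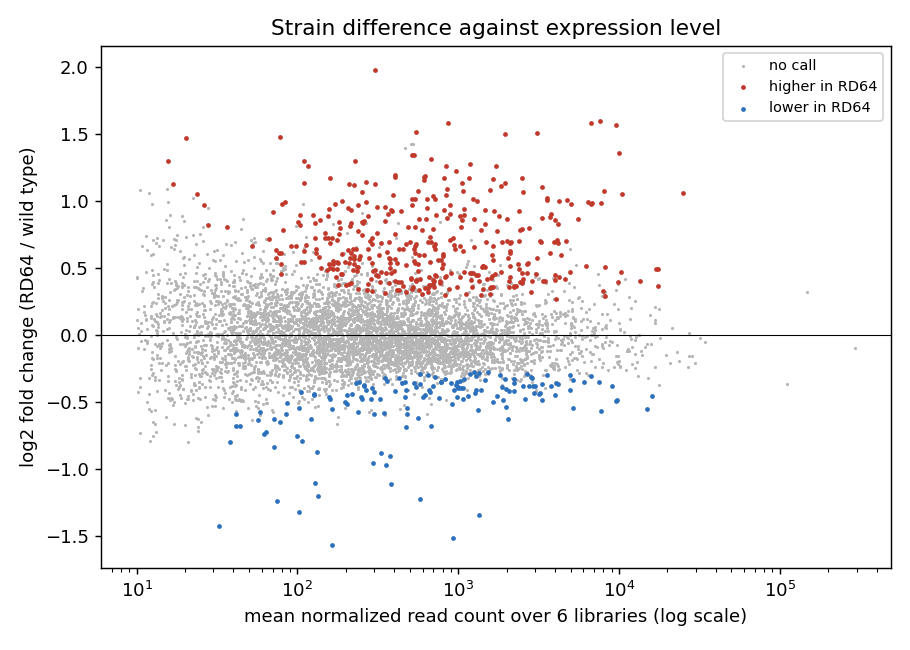
Log2 fold change (RD64 over wild type) of each of the 6012 tested genes against its mean normalized read count over the 6 libraries, on a log axis. Red points are the 393 genes higher in RD64, blue points the 152 lower genes and grey points the genes without a call; the blue points lie mostly within 1 log2 unit of 0, with 10 beyond it.

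Among the called genes, the 2 highest and the 2 lowest limma fold changes lay on pSymB and the chromosome, although a pair of pSymA genes rose by more than either of these 2 lower genes fell, and with edgeR some pSymA genes ranked above SMc04040. SMb20647, on pSymB, rose from 121 ± 12.0 to 487 ± 115 normalized reads (SD, n = 3), a log2 fold change of 1.98 ± 0.154 (SE; limma adjusted p = 0.000571). The chromosomal gene SMc04040 rose from 3804 ± 649 to 11505 ± 1819 normalized reads, a log2 fold change of 1.60 ± 0.145 (adjusted p = 0.000858). Among the lower genes, SMb20171 fell from 243 ± 14.7 to 84.0 ± 25.7 normalized reads, a log2 fold change of -1.57 ± 0.188 (adjusted p = 0.00132). SMb21648 fell from 1371 ± 292 to 481 ± 132 normalized reads, a log2 fold change of -1.52 ± 0.187 (adjusted p = 0.00145). All 4 genes kept their direction and passed the threshold under each of the 18 alternatives, including the removal of any single library. They were chosen among called genes without overlap between strains. Keeping direction without a single library follows from that choice, which also favours passing.

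**Figure D2:**
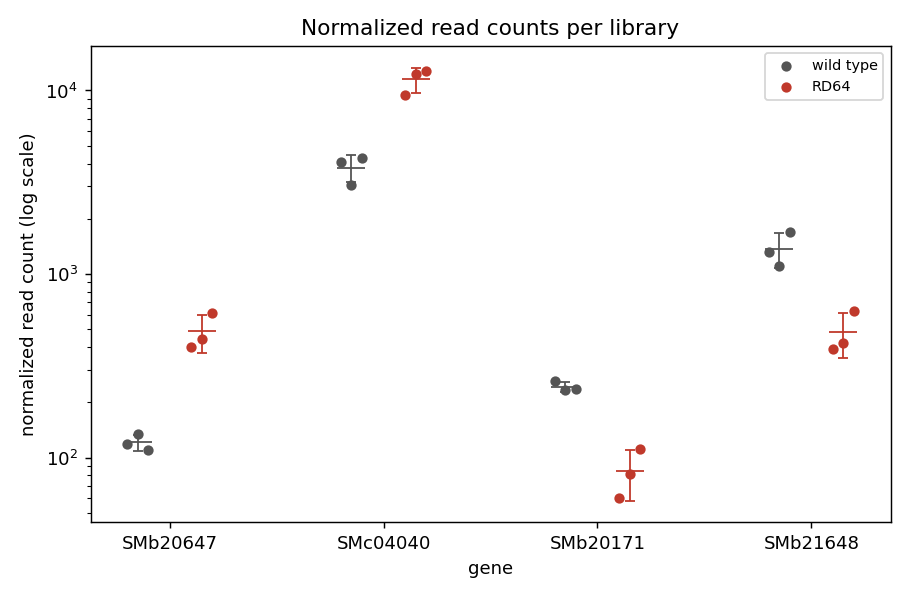
Normalized read counts, on a log axis, of the 2 genes with the highest (SMb20647, SMc04040) and the 2 with the lowest (SMb20171, SMb21648) fold change among genes chosen by the fixed rule. Points are single libraries (grey, wild type; red, RD64), horizontal marks are means and bars are SDs (n = 3); in each gene the 3 RD64 points lie on one side of the 3 wild-type points.

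The replicons contributed unequally to the genes higher in RD64. On pSymA, 127 of 1188 tested genes (10.7%; exact 95% interval 8.99% to 12.6%) were higher and 11 (0.926%; 0.463% to 1.65%) were lower. The chromosome had 219 higher (6.56%) and 98 lower (2.94%) genes of 3337. On pSymB, 47 of 1487 tested genes (3.16%) were higher and 43 (2.89%) were lower. pSymA thus held 19.8% of tested genes but 32.3% of the higher and 7.24% of the lower calls. It also held 41 of the 64 genes that were higher by at least 1 log2 unit. These shares were not adjusted for expression level. Median levels were 98.8 normalized reads on pSymA, 133 on pSymB and 509 on the chromosome. The 1503 genes with the lowest means held 20 higher and 15 lower calls, and the 1503 with the highest held 169 and 73. The few lower calls on pSymA, and the lower share of higher calls on pSymB than on the chromosome, may therefore reflect level. This was not tested. The higher pSymA genes had a median log2 fold change of 0.89, against 0.53 on the chromosome and 0.67 on pSymB. Genes at low levels had larger standard errors and needed larger changes to be called. The order of these medians may therefore also reflect level. The counts of calls depended on single libraries. Higher pSymA genes numbered 31 without wild type b and 36 without RD64 e, and between 87 and 135 without any one of the others. Without wild type b, pSymA held 17.5% of the higher calls, less than its 19.8% of tested genes; without any one of the other libraries it held between 23.8% and 46.1%. Lower pSymA genes numbered 2, 2 and 18 without wild type a, b and c, 5, 1 and 2 without RD64 d, e and f, 17 with quantile normalization and 29 with library quality weights. The genes higher by at least 1 log2 unit included 16 on pSymA of 30 without wild type b, 14 of 43 without RD64 d, 21 of 42 without RD64 e and 85 of 110 without RD64 f. On the chromosome, higher genes numbered 120, 75 and 131 without wild type b, RD64 e and RD64 f, and lower genes 25, 202, 27, 8 and 21 without wild type b, wild type c, RD64 d, RD64 e and RD64 f. On pSymB, higher genes numbered 26, 20 and 27 without wild type b, RD64 e and RD64 f, and lower genes 18, 18, 10 and 25 without wild type b, RD64 d, RD64 e and RD64 f.

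As a set, pSymA genes were shifted toward RD64 relative to the other replicons (limma camera, adjusted p = 0.00126), but not with an inter-gene correlation estimated from the data (adjusted p = 0.196 with an estimated correlation of 0.0344). The camera adjusted p was 0.225 for the chromosome and 0.266 for pSymB. Reads on pSymA genes made up 5.33% ± 0.373 of normalized reads in the wild type and 7.50% ± 1.30 in RD64 (SD, n = 3; exact permutation p = 0.10, the smallest that 3 against 3 libraries allow). The chromosomal share was 83.9% ± 0.465 and 82.0% ± 1.17 (exact permutation p = 0.10), and the pSymB share was 10.7% ± 0.251 and 10.5% ± 0.135 (exact permutation p = 0.60). The shift was not uniform over pSymA. Its median log2 fold change was only 0.08, whereas its 90th percentile was 0.68, against 0.34 on the chromosome and 0.33 on pSymB. Per library, the pSymA median relative to the wild-type mean was 0.08, 0.06 and 0.12 in RD64 and 0.07, -0.04 and 0.00 in the wild type, so it overlapped between strains.

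The higher genes of pSymA were concentrated in one part of the replicon. Counting tested pSymA genes in table order, the bin of genes 501 to 600 held 55 genes higher in RD64 and 0 lower, where permuting the calls gave a median of 16 in the fullest bin and never more than 25 (permutation p = 0.0001, the smallest that 10000 permutations can give). The permutation moved single calls as if genes were independent, whereas 86 higher pSymA genes lay in 13 runs of neighbours. Its counts are therefore lower than clustered calls could give. Genes 301 to 700 held 107 of the 127 higher calls (84.3%) and had a median log2 fold change of 0.28. Of these 400 genes, 26.8% were higher and 3 were lower. Of the other 788 pSymA genes, 20 (2.54%) were higher and 8 were lower, with a median log2 fold change of 0.02. This segment was chosen from the same calls. The segment held between 74.2% and 91.9% of the higher pSymA calls when any one library was left out, but its count of higher genes fell to 66 without wild type a, 23 without wild type b and 30 without RD64 e. The number of higher genes in the bin of 501 to 600 was 28 without wild type a, 4 without wild type b, 33 without wild type c and 10 without RD64 e. The segment median relative to the wild-type mean was 0.31, 0.28 and 0.23 in RD64 d, e and f and 0.08, -0.08 and 0.02 in wild type a, b and c.

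**Figure D3:**
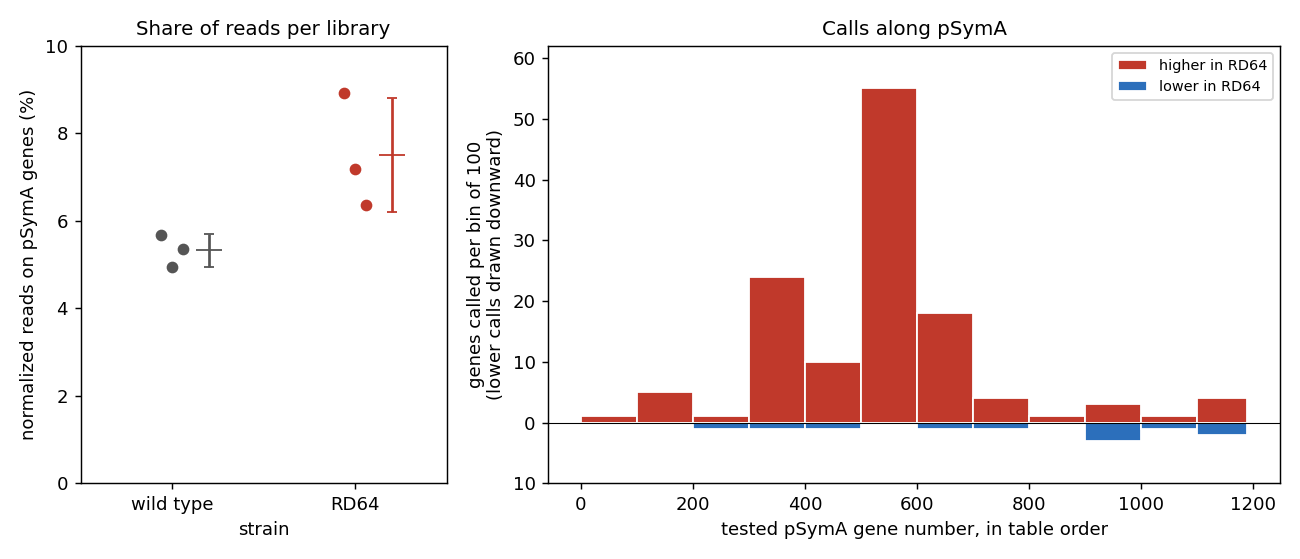
Left, share of normalized reads on pSymA genes in each library (points) with the mean and SD of each strain (n = 3), on an axis from 0; the RD64 libraries lie at 8.93%, 7.19% and 6.37% and the wild-type libraries at 5.68%, 4.94% and 5.36%. Right, number of genes called higher (red, upward) or lower (blue, downward) in RD64 per bin of 100 tested pSymA genes in table order (88 in the last bin), with the peak of 55 at genes 501 to 600.

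Neighbouring genes tended to change together. Of the 393 higher genes, 140 (35.6%) lay in 29 runs of at least 3 adjacent genes called in the same direction, where permuted calls gave a median of 6 and at most 25 such genes (permutation p = 0.0001, the smallest possible). The longest run, on pSymA, spanned 14 genes with log2 fold changes between 0.63 and 1.22. Further pSymA runs spanned 11, 10, 8 and 8 genes, and one of the runs of 8 had the highest median change, 1.30. In all, pSymA held 13 higher runs with 86 genes, the chromosome 13 runs with 44 genes and pSymB 3 runs with 10 genes. Of the 152 lower genes, 24 (15.8%) lay in 6 runs, against a permuted median of 0 and a maximum of 10 (permutation p = 0.0001). The pSymB run that includes SMb21648 had 6 genes with a median log2 fold change of -1.16, and the one that includes SMb20171 had 4 genes with a median of -1.38. The other 4 lower runs, on the chromosome, held 14 genes. Higher genes in runs numbered 82 without wild type a, 38 without wild type b, 88 without RD64 d and 28 without RD64 e, and lower genes in runs numbered 6, 13, 3 and 0 in these fits, 46 without wild type c and 10 without RD64 f. Genes whose annotated ranges overlap can share reads, which may add to agreement between neighbours, and this was not tested. The permutations moved single calls as if genes were independent. Their p-values therefore take genes, not libraries, as the units and do not tell why neighbours changed together.

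**Figure D4:**
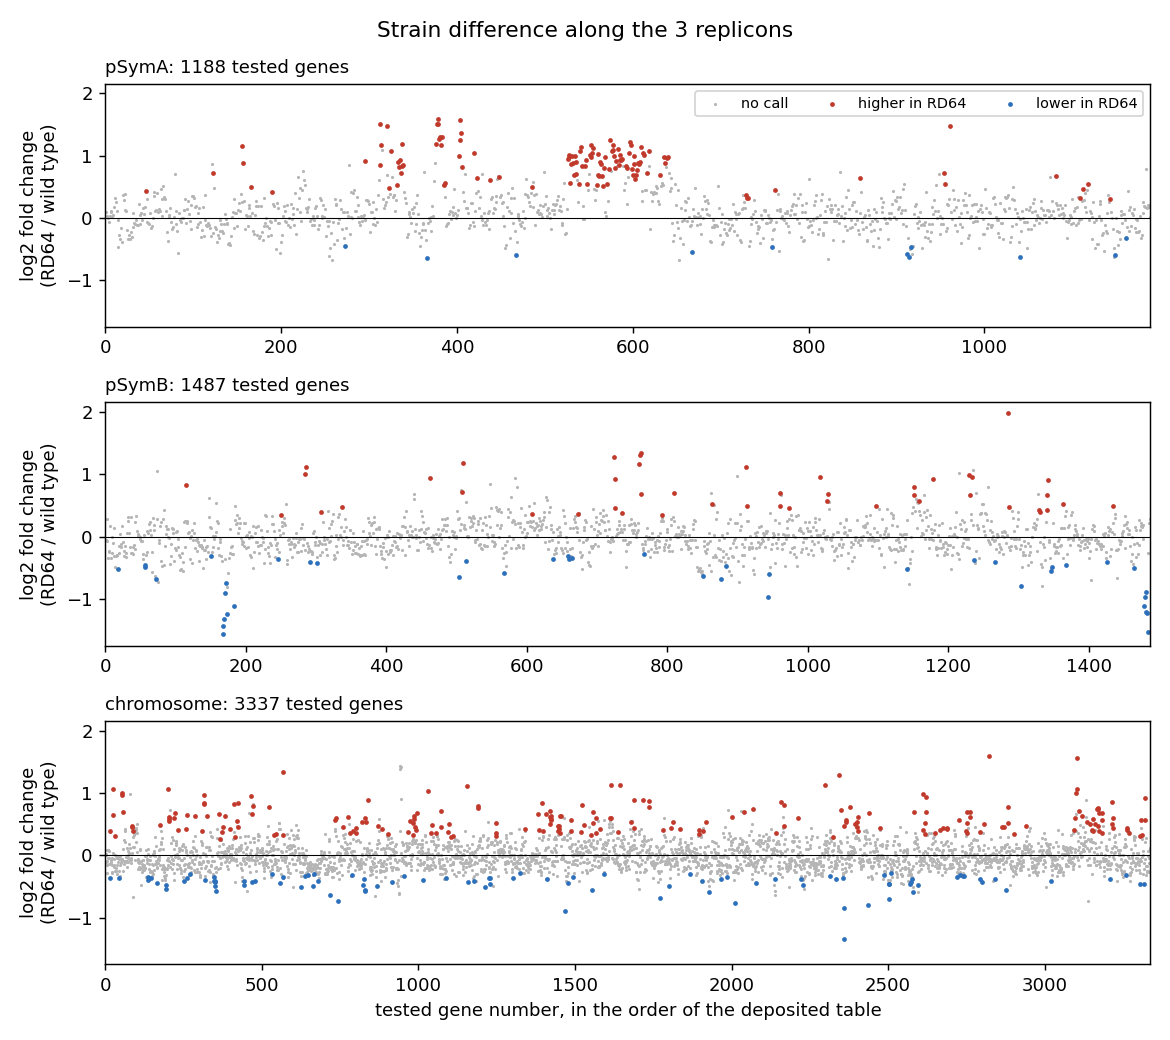
Log2 fold change (RD64 over wild type) of each tested gene, numbered in table order along pSymA (1188 genes), pSymB (1487) and the chromosome (3337). Red points are called higher in RD64, blue points lower and grey points are without a call; red points crowd between genes 501 and 600 of pSymA, and pSymB shows the lower runs of 4 and 6 genes.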

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

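The alternatives were fixed before the data were examined, except keeping the repeated accession rows, thinning to equal depth, leaving out wild type a and RD64 d together, and the values of bins, the pSymA segment, runs, the chromosome, pSymB and the fold changes of called pSymA genes without single libraries. The counts of changed, higher and lower genes stayed within 1.5 times 545, 393 and 152 under both other pseudocounts, both other filters, edgeR, DESeq2, equal depth and with the repeated rows kept. edgeR shared 541 of the 545 calls in direction and DESeq2 500, with 816 adjusted p-values not given by DESeq2. Equal totals gave 230 lower genes and quantile normalization 233. Library quality weights gave 973 changed genes, 611 higher and 362 lower; the cause was not tested. A threshold of 0.01 left 158 changed genes, and a minimum log2 change of 1 left 74, by construction. Leaving out 1 library, which also removes a degree of freedom, gave 150 to 687 changed, 131 to 408 higher, 19 to 279 lower and 31 to 135 higher pSymA genes. Leaving out wild type a and RD64 d together gave 187 changed, 164 higher and 23 lower genes, with 43 higher on pSymA. The pSymA set stayed past the threshold under each of 18 alternatives, but all of them used the preset inter-gene correlation of 0.01. They therefore do not test that setting. With the correlation estimated from the data (0.0344), the call ended (camera adjusted p = 0.196). The tests of the 23 gene lists and the removal of ribosomal and transfer RNA rows were not run for want of gene names. No paired analysis was possible because the replicate letters a to f are all different. Depth limits the 1503 genes with the lowest means most, of which 2.33% were called.

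Grouping the 6 libraries in each of the 10 possible ways gave 545 changed genes for the real split and at most 1 for any other. The more frequent direction held 393 against at most 1, and the less frequent one 152 against at most 0. So 1 of 10 splits was as large each time, and 10 splits are too few for a share under 0.05. Every other split also mixes the strains within its groups, so the strain difference widens their spread. Few calls were therefore to be expected there, and the contrast does not measure chance. For pSymA as a set, 3 of the 10 splits gave a camera value as small as the real 0.000419. The smallest, 1.27e-06, set wild type a, RD64 d and RD64 f against the rest and called 0 genes. This split keeps RD64 d and f together, so it carries part of the strain difference. Its libraries had the highest pSymA medians, 0.0688, 0.0822 and 0.122, with RD64 e close behind at 0.0637. The set test on pSymA thus does not single out the strain split, and it cannot show variation apart from strain.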

Other observations

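Libraries of one strain also varied among themselves; the difference between strains in this spread was not tested, and wild type a was the shallowest library. Among the wild-type libraries, 177 of the 6012 tested genes had a range of at least 2-fold, and among the RD64 libraries 111 did. The median range was 0.29 on the log2 scale in the wild type and 0.19 in RD64. In RD64, 70 of the 111 variable genes were on pSymA, 22 on the chromosome and 19 on pSymB. In the wild type, 62 of 1188 tested genes on pSymA, 69 of 1487 on pSymB and 46 of 3337 on the chromosome were variable. The pSymA count was thus similar in the strains, and the counts on the other replicons were lower in RD64. Expression level differed by replicon, with a median of 509 normalized reads for chromosomal genes, 133 for pSymB and 98.8 for pSymA. Along the chromosome the fullest bin of 100 tested genes, genes 3101 to 3200, held 20 higher genes and 0 lower.

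The tests below of pSymA copy number, of wild type b and RD64 e alone and of lost pSymB segments were chosen only after the values they use had been seen. Leaving out RD64 d was fixed before the data were examined, and the other tests were chosen after the pattern was seen but before their own result.

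The first pattern is the excess of genes higher in RD64 on pSymA, 127 against 11 lower. A higher copy number of the whole of pSymA in RD64 would raise all its genes alike. The median over all pSymA genes was only 0.08 (0.0838), and per library it overlapped between strains. This argues against whole-replicon copy number as the whole cause and leaves a small common shift open. The 0.89 of the called genes is no fair comparison, because large changes are what gets called. The bin of genes 501 to 600 had a median of 0.69, and a higher copy number of only part of pSymA was not tested. RD64 d alone does not account for the excess, since 87 pSymA genes were higher without this library. The median log2 fold change of the 127 genes nevertheless fell furthest without RD64 d, from 0.89 to 0.69. The count fell to 31 without wild type b, where pSymA held 17.5% of the higher calls against 19.8% of tested genes, and to 36 without RD64 e. The fold changes did not fall in this way: the 127 genes, which were called with all 6 libraries, had a median of 0.89 (median SE 0.190) with all libraries, 0.82 (0.816; median SE 0.221) without wild type b and 0.92 (0.917; median SE 0.225) without RD64 e. The median SE was about as large without wild type a (0.223) or c (0.220), where 88 and 97 pSymA genes were higher. It does not by itself account for the lost calls. All 127 genes kept an unadjusted limma p under 0.05 in each of these fits. The largest limma p still called was 0.00184 without wild type b and 0.00124 without RD64 e. It was 0.00447 with all libraries, and 0.00374 and 0.00571 without wild type a and c. The median limma t was 3.64 and 3.95 without b and e, against 4.17 and 4.19 without a and c. Under the Benjamini-Hochberg method the largest p still called is tied to the number of calls, so it restates the loss and does not account for it. The lost calls went with lower t values, and what lowered these was not tested. These medians cannot decide whether wild type b or RD64 e alone is the source of the size of the fold changes. Genes called for a consistent gap over all 6 libraries tend to keep it when 1 is left out. The number of calls depends on both libraries. Lower pSymA genes numbered 2, 2 and 18 without wild type a, b and c and 5, 1 and 2 without RD64 d, e and f. A difference in depth does not account for the excess, since 112 were higher after all libraries were thinned to equal depth. The excess is itself a difference between the strains, and what underlies it was not tested. These 6 libraries hold no strain with the genetic change but without extra IAA, so IAA and other consequences of the change may both be involved.

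The second pattern is that the RD64 libraries differed in the size of the pSymA response. The genes called higher had a median of 1.34 in RD64 d, 0.84 in RD64 e and 0.52 in RD64 f over the wild-type mean. The 90th percentile over all pSymA genes kept this order, at 0.94, 0.67 and 0.52. The median over all pSymA genes did not, at 0.08, 0.06 and 0.12, so the order does not hold for pSymA as a whole. The median over the segment of genes 301 to 700 did keep the order, at 0.31, 0.28 and 0.23. As a hypothesis, RD64 libraries may differ along the same axis as the strains do: across pSymA genes, the difference between RD64 d and f correlated with that between RD64 e and the wild type, libraries not used in the first (Pearson r = 0.483, Spearman rho = 0.270 over 1188 genes, which are not independent replicates). The other 2 differences between RD64 libraries gave a Pearson r of 0.402 (e minus f, against RD64 d) and 0.166 (d minus e, against RD64 f), so the agreement was weak for the last. For d minus f, the correlation was -0.0628 on the chromosome and 0.0636 on pSymB. Depth does not account for the gap, as the 90th percentile of pSymA values differed by 0.423 between RD64 d and f both before and after thinning to equal depth. Within the wild type the largest absolute Pearson r on pSymA was 0.251, too small to tell whether wild-type libraries share this axis. That difference, b minus c against wild type a, gave -0.251 on pSymA, -0.320 on the chromosome and -0.183 on pSymB, so it was not particular to pSymA. By rank, the wild-type differences on pSymA gave a Spearman rho of -0.264 (b minus c), 0.246 (a minus b) and -0.0205 (a minus c). The first and second were nearly as large in size as the 0.270 of RD64 d minus f. Ranks on pSymA thus do not set RD64 apart from the wild type. Culture conditions per library, which the labels do not give, stay open.

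The third pattern is the pair of runs of lower genes on pSymB, 10 genes in all. Loss of these segments of DNA from RD64 would leave them without reads, yet every gene in them had at least 8 reads in each RD64 library, and their RD64 means were 34.5% to 53.8% of the wild type. This argues against a complete loss in all RD64 cells. A loss in part of the cells would leave such intermediate values and was not tested.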
